A study of Mus musculus with 3 samples.

How the data were processed

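H3K27ac, the acetylation of lysine 27 of histone H3 that marks active promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing in mouse embryonic brain at day 9.5. The series holds 3 libraries: 1 H3K27ac library of the control group, 1 H3K27ac library of the group labelled DM, and 1 input library. Per the labels' protocols, tissue was fixed in formaldehyde at 1% for 10 min, chromatin was sheared by sonication, and sequencing libraries were built from 10 ng of DNA. With 1 library per group there is no replicate, so no p-value, standard error or count of changed regions from a test is given as a result, and every difference below is one between 2 libraries. The authors' test was run again only to find its settings.

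The deposited table lists 57157 regions, each a union of peaks called separately in the control and DM libraries, with the coordinates of the peaks of each library, a read count per library, a log2 fold change, a p-value, an adjusted p-value and a gene annotation. Bowtie2 and the build mm9 are named in the submitters' processing notes, without a version or a role. The peak caller, the counting tool and the test are not given in the sources used here. The coordinates fit the later build GRCm38: of 7173 regions annotated within 1 kb of a promoter whose symbol is in a GRCm38 gene table, 98.4% lie on that gene or within 1000 bp of it. Coordinates are given as in the deposited table. Gene symbols are those of the table, and 88.2% of its regions carry a symbol that is also in the GRCm38 gene table.

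The read counts deposited by the authors are whole numbers and are not scaled. A count of 0 stands exactly where the table lists no peak for that library, and the smallest other counts are 14 reads in the control and 15 in DM. A 0 was therefore read as no peak called, not as a measured absence of signal, and no fold was computed for a region with a peak in 1 library only. In shares and counts of lower and higher regions, such a region follows the authors' call: lower if control only, higher if DM only. For these regions the words state where a peak was called, not a measured change. In regions with a peak in both, the count covers the bases called in each library, which differ between the libraries. Reads per called base were therefore computed beside the reads per region, as a measure chosen after the data were seen. Each library was divided by its own called bases, so where the widths differ this ratio sets a narrow peak against a wider one. It is not a ratio over the same bases, and a value near or above 0 does not show that signal over the wider peak was unchanged or higher. This ratio was computed only with the scaling to the control total described below, so its sign holds for that scaling.

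The authors' deposited log2 fold changes were matched to within 4.46e-11 by a formula with a prior count of 0.125 and a library-size ratio, control over DM, of 1.48. The authors' deposited p-values were matched, in 2000 regions, to within 4.97e-08 on the log10 scale by the exact test of edgeR 4.0.16 with a coefficient of variation between replicates set to 0.1, a value that cannot be estimated from 1 library per group. With 0.4 in its place, 1242 of the 7249 regions with a peak in both libraries have a p-value under 0.05. The relation of the authors' deposited adjusted p-values to the p-values implies 78968 regions tested, so 21811 regions are not listed. The table is a selected one: its smallest absolute log2 fold change is 1.00 and its largest p-value is 0.0438.

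DM counts were multiplied by 1.38, which brings the total over the listed regions from 1858774 reads to the 2567340 reads of the control. This total covers listed regions only and is not the sequencing depth, which is unknown here. A log2 ratio of DM over control was computed for each region with a peak in both, with an exact (Clopper-Pearson) 95% interval of the ratio given the counts. Intervals on shares are exact binomial 95% intervals. Both cover counting error only. Regions entered when the mean of the scaled counts was at or above its lower quartile of 18.5 reads, with 0 for a library without a peak. This minimum removed 4694 of the regions called in DM only, 9161 of those called in the control only and 0 of those called in both, so shares that include regions of 1 library are also given without it where they move.

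Per gene, the listed promoter region with the highest mean signal was taken as the leading region. For 18 gene lists the median log2 ratio, and the share of members whose leading promoter region was lower in DM, were set against 10000 random lists of the same size matched in 20 bins of mean signal, and are given as percentiles that describe these libraries. The lists, the scaling, the minimum and the rule for named genes were fixed before the data were examined. The share lower was added afterwards. The lists were first computed without the signal minimum by oversight, and the planned minimum was applied after those percentiles had been seen. Both sets of percentiles are therefore given wherever a list lies near the 95% limits. Named genes are Acly with its list, the 10 genes with the highest and the 10 with the lowest log2 ratio (predicted genes, Rik names, unnamed clones and chromosomes other than 1 to 19 and X left out), and the 2 highest and 2 lowest members of each list. Genes with a peak in 1 library only have no ratio. Those named were chosen after their values were seen, except Acly. Some genes that the rule would name are not reported here.

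Tests on simulated counts with the means of the 7249 regions returned 99.5% of 4-fold changes as at least 2-fold in the right direction and 0.0993% of unchanged regions as at least 2-fold. The interval held the true ratio in 96.0% of regions. These counts held Poisson counting error only, with no variation between libraries and no difference in called width. The rates therefore say nothing about how many differences between the real libraries are false. For the percentiles of list medians, simulated on 2500 genes, 3 of 100 unshifted lists lay outside the central 95%, and 100 of 100 lists shifted by 1.5 on the log2 scale lay above it. Those ratios were drawn from a normal distribution, unlike the ratios of the selected table, and the share lower was not simulated. Alternatives were 2 other scalings (trimmed mean of M values, TMM, and median of ratios), no minimum, regions above the median signal, a pseudocount of 26.2 reads, 1.5-fold and 4-fold thresholds, other choices of the region per gene, and a stricter set or overlap of peaks. Those chosen after the data were seen were the authors' library-size ratio, reads per called base, and regions of 1 library counted with 0. The input library has no column in the table, so enrichment over input was not analysed here. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and matplotlib 3.10.9.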

Results

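H3K27ac was profiled in embryonic mouse brain at day 9.5, in 1 control library and 1 library labelled DM. The series concerns maternal diabetes, neural tube defects and ATP citrate lyase, the enzyme that makes cytosolic acetyl-CoA from citrate. The control library had 2567340 reads in 28551 listed regions with a peak, and the DM library 1858774 reads in 35855. Counts were 14 to 4103 reads per region in the control and 15 to 1306 in DM. There was no replicate, so no difference below could be set against the spread between embryos or libraries, and all intervals cover counting error only.

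The first comparison asks where H3K27ac was found in each library. More regions had a peak in the DM library only (28606) than in the control library only (21302), and 7249 had a peak in both. The control-only regions were wider, with a median of 443 called bases and 39 reads, against 326 bases and 35 reads for the DM-only regions. The shortest called peak was 311 bases in the control and 239 in DM. Of the listed regions, the authors' deposited table calls 32577 higher and 24580 lower in DM, and 87.3% of these calls rest on a region with a peak in 1 library. Their absolute log2 fold changes, from 6.57 to 12.4 in the authors' deposited table, come from a prior count set against 0. The largest in a region with a peak in both is 3.99. Of the listed regions with a p-value at or below the median in the authors' deposited table, 20371 had a peak in DM only, 7539 in the control only and 992 in both.

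Among the 7249 regions with a peak in both libraries, 3334 were at least 2-fold higher and 3278 at least 2-fold lower in DM, with log2 ratios from -4.09 to 3.68. The whole interval lay beyond 2-fold in 1011 of the higher and 1798 of the lower regions. The read ratio followed the ratio of called lengths across these regions (Pearson's r = 0.927 across 7249 regions, which are not independent replicates). Reads were counted within the called bases, so these ratios are linked by construction. The fold threshold of the table also leaves a gap between higher and lower regions, which can raise r. In the regions that the authors' deposited table calls lower, the median was 61 reads over 503 called bases in DM and 257.5 reads over 1528.5 called bases in the control, or 123 against 173 reads per kb before scaling. In those it calls higher, the medians were 78 reads over 752 bases in DM and 40 reads over 459 bases in the control, or 105 against 84.2 reads per kb. Per called base, 1050 regions were at least 2-fold higher and 91 at least 2-fold lower. The median log2 ratio per called base was -0.02 in the regions at least 2-fold lower by reads and 0.78 in those at least 2-fold higher. With median-of-ratios scaling, which shifts every log2 ratio by -0.95, 388 regions were at least 2-fold higher and 3278 at least 2-fold lower, and 347 changed direction. That scaling takes the median region as unchanged, whereas the table lists only regions past its fold threshold. Its shift thus depends on the selection, and its values show a dependence on scaling only. With a pseudocount the numbers were 1545 higher and 2697 lower.

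Promoters and gene bodies went in opposite directions. Promoters made up 68.2% (95% interval 66.5 to 69.7) of the regions at least 2-fold lower in DM, but 10.8% (9.79 to 11.9) of those at least 2-fold higher. They were 26.9% (26.1 to 27.7) of the control-only regions and 9.27% (8.90 to 9.64) of the DM-only regions above the signal minimum, where introns were 31.9% (31.1 to 32.8) and 53.4% (52.8 to 54.1). Of 8143 promoter regions 67.5% (66.5 to 68.5) were lower in DM, against 22.3% (21.7 to 22.9) of 18906 intronic and 35.0% (34.1 to 35.9) of 10904 distal intergenic regions. These shares depend on which weak regions of 1 library are counted: without the minimum 69.2% of promoters and 31.7% of introns were lower, and with median-of-ratios scaling 78.5% and 43.2%. With the direction taken per called base 56.9% and 21.1% were lower. This could change only regions with a peak in both, 2664 of the promoter and 2252 of the intronic regions, and left the others as called. Among regions with a peak in both, the median log2 ratio was -1.33 at promoters and 1.19 in introns. Per called base it was -0.02 at promoters and 0.74 in introns.

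**Figure D1:**
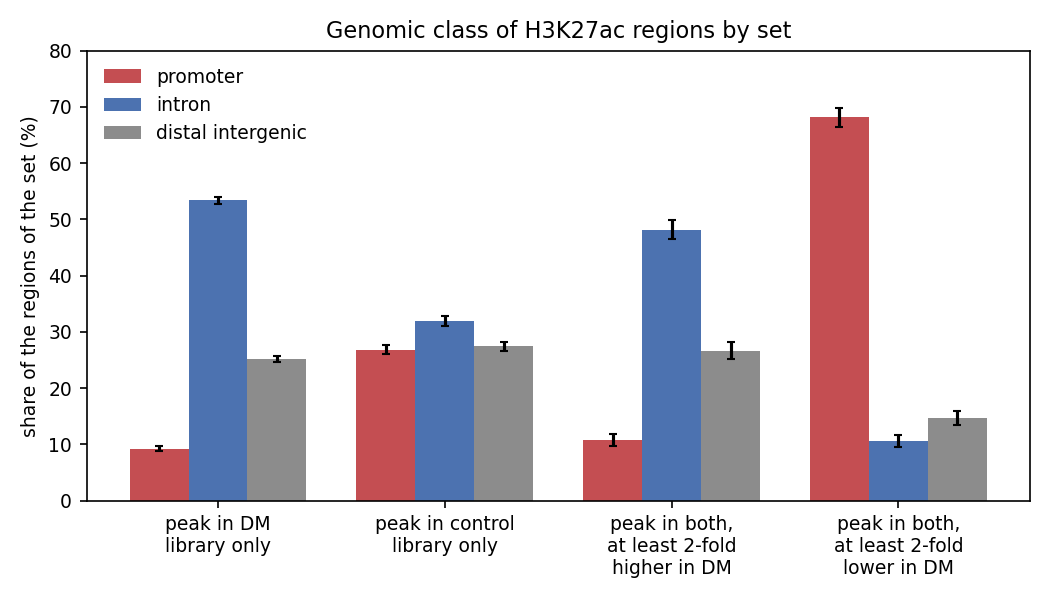
Share (%) of promoter, intron and distal intergenic regions among the H3K27ac regions above the signal minimum in each of 4 sets, with exact binomial 95% intervals as error bars (counting error only). Promoters make up 68.2% of the regions at least 2-fold lower in the DM library and 9.27% of those called in the DM library only.

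At the level of genes, the leading promoter region was lower in DM in 4689 of 6498 genes (72.2%) and higher in 1809. A promoter region under the authors' fold threshold is not listed, so the leading region need not be the main promoter of the gene. The same limit holds for the named genes and lists below. In 2517 genes the leading region had a peak in the control only, in 1444 in DM only, and in 2537 in both, of which 2172 were lower and 365 higher. Outside promoters the direction turned: the leading region was lower in 35.5% of 10705 genes. Over all regions, 40.1% of 14021 genes had more lower than higher regions, with ties counted as not lower.

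The lowest ratio belonged to Trim66 (ENSMUSG00000031026; chromosome 7, 109492106 to 109494917), with 28 reads in DM and 434 in the control and a log2 ratio of -3.49 (-4.09 to -2.94). Next came Gprc5c at -3.35, Fgfbp1 at -3.28, Mlx at -3.25 and Tsc1 at -3.24. Mlx is the dimerisation partner of the glucose-responsive transcription factors of the Mondo family, and Tsc1 restrains mTORC1. Slc7a11, the cystine/glutamate exchanger, stood at -3.04 (-3.47 to -2.64; 54 against 615 reads; chromosome 3, 50441867 to 50445009). Slc7a1, a transporter of cationic amino acids, stood at -2.88 (-3.47 to -2.35; 31 against 316 reads). Gripap1 (-3.02), Utp14a (-2.92), both on X, and the Wnt receptor gene Fzd1 (-2.91) completed the 10. In Trim66 the DM peaks covered 247 bases and the control peaks 2812, and per called base the log2 ratio was 0.02. Per called base Slc7a1 remained lower at -1.04, Fzd1 at -0.71, Slc7a11 at -0.62, Mlx at -0.52 and Gripap1 at -0.23, whereas Trim66, Gprc5c, Fgfbp1, Tsc1 and Utp14a lay between 0.02 and 0.35.

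The highest ratio belonged to Trak1, an adaptor for mitochondrial transport (ENSMUSG00000032536; chromosome 9, 121367033 to 121368561), with 172 reads in DM and 29 in the control and a log2 ratio of 3.03 (2.46 to 3.66). The cytokine gene Il10 followed at 2.97 (2.54 to 3.43; 290 against 51 reads), then Aoc3 at 2.74, Smgc at 2.54, Ttc7 at 2.52, Nav2 with 127 against 31 reads, Icam4 at 2.48, Acp6 at 2.46, Rin2 at 2.37 and Tbc1d1 at 2.34. Per called base all 10 remained higher, from 0.32 in Il10 to 1.47 in Trak1.

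**Figure D2:**
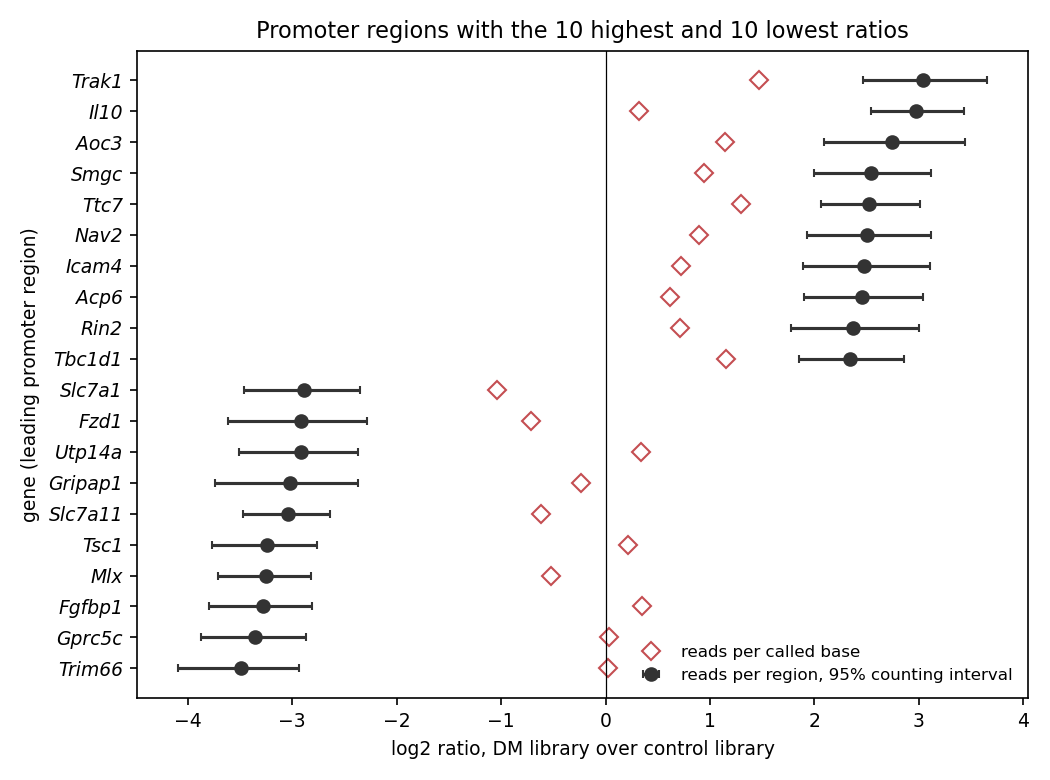
Log2 ratio of the DM library over the control library in the promoter regions with the 10 highest and 10 lowest ratios. Filled circles are reads per region with 95% counting intervals, open diamonds reads per called base. By reads Trim66 lies at -3.49 and Trak1 at 3.03, and per called base they lie at 0.02 and 1.47.

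Acly itself (ENSMUSG00000020917) had no listed promoter region. The table holds only regions past the authors' thresholds, so this leaves open whether its promoter had a peak. Its 1 listed region was 424 bases long, in intron 15 of 28 (chromosome 11, 100500979 to 100501402), with a peak of 63 reads in DM and no peak called in the control. In its list, acetyl-CoA and lipid synthesis, 11 of 26 members had a promoter region above the minimum, of which 10 were lower and 1 higher in DM. Acaca, which makes malonyl-CoA from acetyl-CoA, had a log2 ratio of -1.41 (-1.81 to -1.03; 72 against 265 reads). Insig1, a sterol sensor of the SREBP pathway, was at -1.28 (-1.44 to -1.12), and the citrate synthase gene Cs at -1.10 (-1.36 to -0.85). Per called base Acaca stood at -0.11 and Insig1 at -0.52, but Cs was higher at 0.19. Slc25a1, the mitochondrial citrate carrier, and Sqle had a promoter peak in the control only, with 47 and 165 reads. Acacb had one in DM only, with 29 reads. The share lower lay at percentile 78.2 and the median log2 ratio of 6 members, -1.34, at percentile 59.4 of matched random lists. Per called base that median was -0.28. Outside promoters 51 regions of the list were higher and 25 lower.

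Genes of histone acetylation and its readers were split at promoters, with 8 lower and 7 higher of 15. This share lower lay at percentile 2.26 of matched lists, and at 3.03 without the signal minimum. The acetyltransferase genes Kat6b (-1.39; -1.72 to -1.08), Kat7 (-1.37; -1.58 to -1.16) and Kat8 (-1.17; -1.50 to -0.85) were lower. The deacetylase gene Hdac4 was higher at 1.52 (0.84 to 2.22; 58 against 28 reads). Promoter peaks in DM only were found, among others, at Ncor1 (38 reads), Hdac7 (49), Hdac5 (33), Sirt2 (49) and Brd3 (39). Ncor1 is a corepressor that recruits deacetylases. Promoter peaks in the control only were found at Hdac3 (157 reads), Sirt6 (144) and Sirt1 (57). Per called base Kat6b stood at -0.25, Kat7 at -0.40, Kat8 at -0.15 and Hdac4 at 0.98. The median log2 ratio of 6 members was -1.24, at percentile 69.4, but -0.32 per called base and -2.19 with median-of-ratios scaling.

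Of 58 genes whose loss is known to disturb neural tube closure, 21 had a promoter region above the minimum, 18 lower and 3 higher in DM. The share lower, 85.7%, lay at percentile 96.1 of matched lists, and at 97.6 without the minimum, where 20 were lower and 3 higher. Zic2, a transcription factor of the dorsal neural tube, was lower at -1.57 (-2.15 to -1.02; 34 against 139 reads; chromosome 14, 122475388 to 122476811). The actin regulator Vasp was at -1.54 (-2.11 to -1.01) and the folate receptor gene Folr1 at -1.14 (-1.54 to -0.75). Shroom3, which drives apical constriction, was higher at 1.15 (0.54 to 1.77; 61 against 38 reads), and outside its promoter 27 regions were higher and 2 lower. Control-only promoter peaks lay at the planar polarity genes Celsr1 (53 reads), Scrib (79), Dvl2 (68) and Fzd6 (93), and at Map3k4 (199). Ptch1 and Bcl10 had DM-only promoter peaks of 43 and 33 reads. Per called base Zic2 (0.41), Vasp (0.15) and Folr1 (0.61) were not lower, over 361, 400 and 741 called bases in DM against 1424, 1297 and 2483 in the control. The median of the 8 members with a ratio was -1.32 by reads and 0.12 per called base. Outside promoters the list had 233 higher and 44 lower regions.

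Promoters of neural progenitor genes were lower in 4 of 5 cases (percentile 51.1). Sox2 was at -1.14 (-1.33 to -0.95; 320 against 973 reads; chromosome 3, 34646459 to 34649758), Cdh2 at -1.36 (-1.66 to -1.06) and Gli2 at -1.35 (-1.76 to -0.95). Per called base Sox2 remained lower at -0.44, whereas Cdh2 lay at 0.01 and Gli2 at -0.03, and the median of these 3 went from -1.35 by reads to -0.03. Pax6 had a control-only peak of 51 reads and Rfx4 a DM-only peak of 35. Regional patterning genes were scarcely listed: 12 of 37 had any region, and 1 promoter, of the hindbrain gene Egr2, passed the minimum, with a control-only peak of 105 reads. Neuronal genes were split, with 3 promoters lower and 3 higher (percentile 12.8). Ebf1 was lower at -1.45 (-1.77 to -1.15) by reads and higher at 0.46 per called base, and 36 of its other regions were higher and 0 lower. The Notch ligand gene Dll3 was higher at 1.21 (0.88 to 1.55; 0.47 per called base), Elavl2 and Elavl4 had DM-only peaks of 40 and 35 reads, and Tubb3 and Stmn2 control-only peaks of 39 and 37.

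Promoters from the lists made for other cell types that embryonic brain tissue could hold were few. Hox genes in these lists do not by themselves mark tissue outside the brain. Somite, heart and Hox genes had 4 promoters, all higher in DM (percentile 0.225; 0.15 without the minimum). They were Hoxd3 at 1.16 (0.89 to 1.43; 294 against 182 reads; chromosome 2, 74730319 to 74732207) and Hoxd4, Hoxb1 and the somite gene Tcf15 with DM-only peaks of 46, 39 and 34 reads. Endothelial Tek and Egfl7 had DM-only promoter peaks of 44 and 38 reads, as did the epithelial gene Epcam with 51. Without the minimum the endothelial list had 2 promoters higher and 1 lower (percentile 24.7). Outside promoters it had 12 regions higher and 4 lower, with 0 higher and 2 lower at Tek. In the neural crest and mesenchyme list Pdgfrb was lower at -1.77 (-2.46 to -1.14) by reads but higher at 0.47 per called base, with 25 reads over 258 bases in DM and 118 over 1225 in the control, and Tbx15 had a control-only peak of 83 reads. The blood list had 0 promoters and the sex-linked list 0 listed regions.

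In the apoptosis and p53 list all 7 promoters were lower in DM (percentile 88.8), among them Foxo3 at -1.81 (-2.08 to -1.54), the pro-apoptotic Bax at -1.71 (-2.02 to -1.40), Mdm2 at -1.14 and Bbc3 at -1.13. In the list of endoplasmic reticulum and oxidative stress 14 were lower and 2 higher (percentile 45.9), with Atf6 at -2.03 (-2.46 to -1.62), the chaperone gene Calr at -1.89 (-2.09 to -1.69), Herpud1 at -1.27 and Trib3 at -1.15. Xbp1 had a control-only promoter peak of 719 reads. In the glucose and hypoxia list 10 were lower and 4 higher (percentile 22.6). The glucose transporter gene Slc2a1 was at -1.50 (-1.91 to -1.10), Ddit4 at -1.40 (-1.52 to -1.28), Aldoa at -1.12 and Hk2 at -1.10. Per called base Atf6 and Aldoa were higher, at 0.39 and 0.24, and the other genes with a ratio named from these 3 lists remained lower, from -0.79 in Ddit4 to -0.26 in Slc2a1. Vegfa had a control-only peak of 309 reads and Hif1a one of 131. Txnip, a glucose-induced inhibitor of glucose uptake (ENSMUSG00000038393; chromosome 3, 96557006 to 96559205), had a DM-only promoter peak of 235 reads, and Ldha, Pdk1 and Hk1 had DM-only peaks of 46, 49 and 36 reads.

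In the cell cycle list 8 promoters were lower and 3 higher (percentile 25.4), with Ccna2 at -2.15 (-2.67 to -1.67) and Cdk4 at -1.68 (-1.87 to -1.49), against Myc at 1.03 (0.62 to 1.45) and Top2a at 1.37 (0.70 to 2.06). In the Wnt list 8 were lower and 3 higher (percentile 37.9), with Fzd1 at -2.91 (-3.62 to -2.28), Tcf7 at -1.47 and Apc at -1.16, against Wnt5b at 1.74 (1.14 to 2.36). Per called base Ccna2 lay at -0.17 and Cdk4 at -0.24, against Myc at 0.67 and Top2a at 0.56. Of the Wnt genes, Apc was higher at 0.26 by that measure, and Tcf7 lay at -0.07, Fzd1 at -0.71 and Wnt5b at 0.74. Housekeeping genes gave 16 lower and 1 higher (percentile 55.6), with Atp5b at -1.75, Sdha at -1.62 and Ncl at -1.11, and Tbp, the higher one, at 2.01 (1.31 to 2.76). Over the 12 lists with a percentile of the share lower, 2 lay outside the central 95%, histone acetylation and somite, heart and Hox. Without the minimum 2 of 14 did, neural tube closure and somite, heart and Hox. The medians of the 10 lists with at least 3 ratios lay between percentiles 27.6 and 96.4, and 0 lay outside the central 95%. With median-of-ratios scaling these medians lay between -2.41 and -2.13. Per called base the median was -0.50 in apoptosis, -0.39 in stress, -0.56 in glucose and hypoxia, -0.13 in cell cycle, -0.07 in Wnt and -0.65 in housekeeping. Across the genes with a ratio named here, 29 of 44 lower ones were also lower per called base, and 18 of 18 higher ones were higher. These signs were read against 0 with the scaling to the control total, and another scaling was not run per called base. Median-of-ratios scaling shifts every log2 ratio by -0.95. The median per called base over autosomal regions with a peak in both was 0.54. Values between 0 and 0.54 are therefore higher by sign only, and lie below that median.

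**Figure D3:**
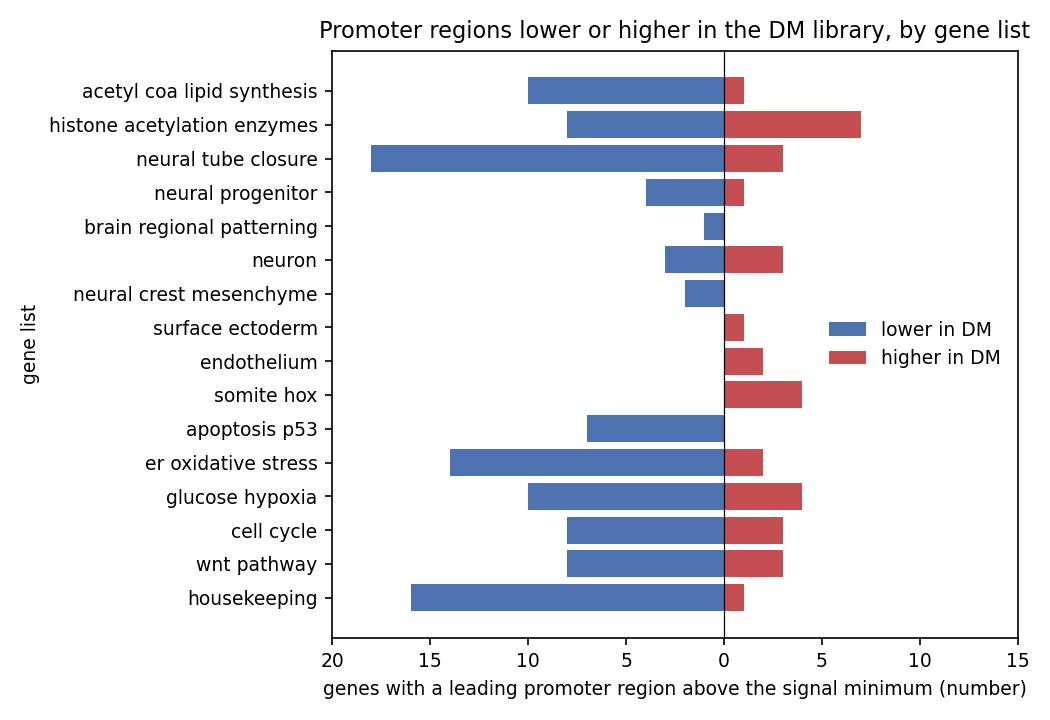
Number of genes in each list whose leading promoter region was lower (left) or higher (right) in the DM library, counting regions with a peak in either library above the signal minimum. Neural tube closure has 18 lower and 3 higher, histone acetylation enzymes 8 and 7, and the somite, heart and Hox list 0 and 4.

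By chromosome, 34.8% to 53.3% of the listed regions were lower in DM on the 19 autosomes, with 42.4% over all of them. On X 736 of 904 were lower, or 81.4% (78.7 to 83.9), but only 162 of the 904 had a peak in both libraries. Most of these calls therefore state where a peak was called. Per called base, the 162 regions of X with a peak in both libraries had a median log2 ratio of 0.12, against 0.54 on the autosomes, and the lower ones among them -0.0014, against -0.02. Y had 2 listed regions, both in introns of Erdr1 and lower in DM, with control-only peaks of 63 and 72 reads.

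**Figure D4:**
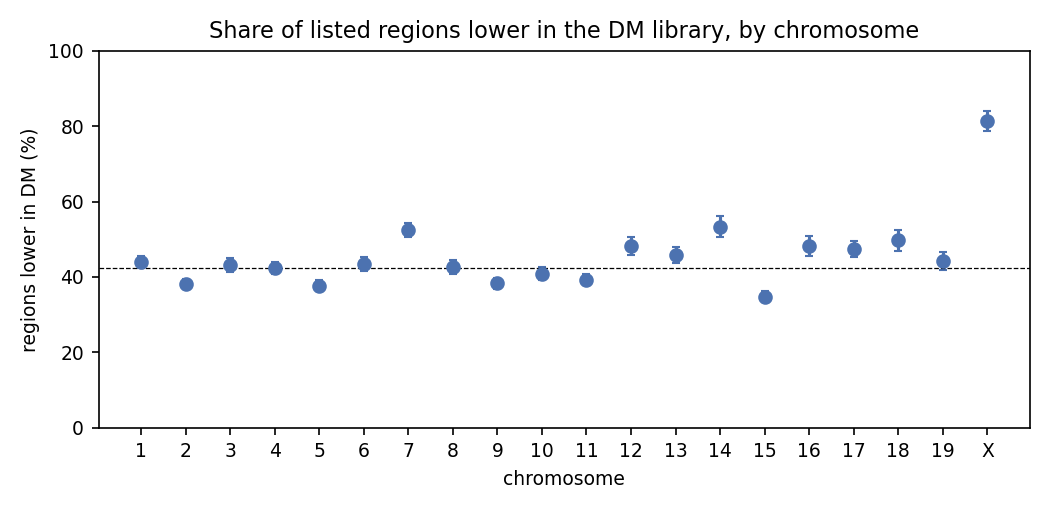
Share (%) of listed regions that are lower in the DM library on each chromosome, regions with a peak in the control only included, with exact binomial 95% intervals (counting error only). The dashed line is the autosomal share of 42.4%, and X lies at 81.4%.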

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

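The settings named as the authors' library-size ratio, reads per called base and regions of 1 library counted as 0 were chosen after the data were seen. The lists, too, were first computed without the signal minimum, and the planned minimum was applied once those percentiles were known. It moved neural tube closure from percentile 97.6 to 96.1 and histone acetylation from 3.03 to 2.26, so neither position relative to the 95% limits holds in both versions. No paired analysis was possible because each group has 1 library. Input subtraction and enrichment over input were not run, since the table has no input column. Regions with a peak in 1 library had medians of 39 and 35 reads, and the sequencing depth is unknown. Where no cause is named below, the cause was not tested.

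Promoters were more often lower than introns with the other scalings and other minimums. They were so per called base too, but regions of 1 library kept their direction there, so that outcome was largely fixed in advance. A pseudocount cannot turn a direction, and neither it nor the called length touches regions of 1 library, so neither was applied there. Other minimums kept all 7249 regions with a peak in both, so they do not test values of those regions, and the table's own fold threshold holds the 3278 lower regions fixed under each scaling. Promoters were a larger share of the lower than of the higher regions with the pseudocount and per called base. With TMM scaling 66.3% of promoters and 20.8% of introns were lower. With median-of-ratios scaling, whose shift depends on the selection of the table, the regions at least 2-fold higher went from 3334 to 388. Promoters were then 22.1% of control-only regions and 6.70% of those at least 2-fold higher, and 78.5% of promoters, 43.2% of introns and 82.1% of genes were lower. Without the minimum promoters were 21.6% of control-only regions, and 69.2% of promoters and 31.7% of introns were lower. Above the median signal these 3 values were 33.3%, 71.6% and 18.5%, with 75.6% of genes lower. With the authors' library-size ratio they were 27.9%, 66.0% and 19.9%, with 70.9% of genes. The pseudocount left 1545 regions at least 2-fold higher and made promoters 73.5% of the lower ones. Reads per called base, computed with the scaling to the control total only, left 1050 higher and 91 lower, with promoters 87.9% of the latter. With regions of 1 library left as called, 56.9% of promoters, 21.1% of introns and 59.4% of genes were lower. At 4-fold 347 were higher and 343 lower, by construction fewer. Counting regions of 1 library as 0 gave 27246 higher and 15419 lower, by construction more. The regions at or below the median p-value held 992 regions with peaks in both and 7539 with a peak in the control only. The overlap of at least 50% of the shorter peak left 6746 of 7249 shared.

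The region chosen per gene turned directions. Over all regions, a gene counted as lower where more of its regions were lower than higher, with ties as not lower. The share lower was then 40.1% of genes. It was 40.9% in the acetyl-CoA list, 23.8% in histone acetylation, 20% in neural tube closure, 30.8% in neural progenitors, 41.7% in apoptosis, 36.0% in glucose and hypoxia, 47.6% in cell cycle and 30.0% in Wnt. Median log2 ratios, from the mean over a gene's regions with a peak in both, became 0.95 in histone acetylation, 0.98 in neural tube closure, 0.18 in neural progenitors and 0.57 in glucose and hypoxia. Outside promoters, the share lower was 35.5% of genes. It was 30.0% in the acetyl-CoA list, 15.8% in histone acetylation, 14.7% in neural tube closure, 45.5% in neural progenitors and in housekeeping, 20% in apoptosis, 46.7% in stress and in cell cycle, 36.4% in glucose and hypoxia and 26.3% in Wnt. Median log2 ratios there were 0.92 in the acetyl-CoA list, 1.34 in histone acetylation, 1.21 in neural tube closure, 1.11 in neural progenitors, 1.13 in stress, 1.20 in glucose and hypoxia, 1.21 in Wnt and 0.0935 in housekeeping. Per called base the neural tube closure median was 0.12. Over all list values under an alternative, 111 stayed, 22 moved and 31 reversed, the last being those given here.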

Other observations

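Of the tests below, the ones on reads per called base and on the members in no earlier list were chosen after the results were seen. The other tests were fixed before theirs.

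Of the 36141 listed regions outside promoters at named genes, without the signal minimum, 64.2% were higher in DM. The genes below were chosen after their values were seen, by the difference between their numbers of higher and lower regions, which grows with the number of regions listed for a gene. Whether higher regions gather at some genes beyond that share or the length of the gene was not tested. Msi2, an RNA-binding protein of neural progenitors, had 85 higher and 10 lower regions outside its promoter, and Trio, a guanine nucleotide exchange factor of axon guidance, 62 and 8. Tanc1 and Pdzrn3 had 51 higher and 2 lower each, Ext1, which builds heparan sulfate, 54 and 7, and Aff1 49 and 2. These 6 genes had the largest excess of higher over lower regions. The excess at genes with more lower regions was smaller, and it was largest at Skap1 with 15 lower and 2 higher, Sntg1 with 15 and 3, Dpp6 with 36 and 26 and Mterf1b with 10 and 0. Myh9 had 19 lower and 11 higher.

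Promoters of the amino acid response, the genes that ATF4 induces when amino acids are short, were lower in DM. After 14 such genes were noticed, among them Asns with a control-only promoter peak of 348 reads, Atf4 with 447 against 1841 reads and Sars with 692 against 3220, a list of 42 further genes of this response was written before their values were seen, 3 of them also members of lists fixed earlier. Of these, 28 had a promoter region, and 28 of 28 were lower, against a median of 89.3% in random lists matched on signal. Among them were the tRNA synthetase genes Lars (74 against 564 reads; log2 ratio -2.46) and Eprs (65 against 412; -2.20), the tRNA exporter gene Xpot (134 against 845; -2.19), Stc2 (46 against 413; -2.70) and Chac1 (100 against 496; -1.84), and Atf3 with a control-only peak of 134 reads. Per called base Lars and Stc2 were higher, at 0.11 and 0.13, and Eprs, Xpot and Chac1 remained lower, at -0.48, -0.54 and -0.22. The share lower lay at percentile 98.1, with and without the signal minimum and also over the 26 in no earlier list. A share of 28 of 28 is the ceiling, and random lists that also reached it were counted partly below it. This percentile therefore argues only weakly against a property that all promoters of that signal share. The median log2 ratio of 22 held-out members, -1.44, lay at percentile 4.63, inside the central 95%, and per called base it was -0.46, at percentile 28.8, so a smaller acetylated width of these promoters in the DM library may account for the pattern as well as a lower density. A difference between embryos, litters or dissections stays open as untested, since each group is 1 library.

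Promoters were mostly lower and other regions mostly higher in the DM library, and of the regions with a peak in both and at least a 2-fold difference, 14.1% kept it in the same direction per called base (2.78% of the lower and 25.3% of the higher), consistent with counts that follow the called width. A weaker enrichment of the DM library could lower strong regions and raise weak ones whatever their class, but at matched signal the share lower at promoters exceeded that elsewhere by 43.4 percentage points, with shuffled classes between -2.43 and 2.46. In regions called in 1 library it exceeded it by 23.3 points at matched reads per called base, with shuffled classes between -0.825 and 0.781. There the DM densities were scaled up and the control densities were not. Near the low end, control-only regions had 60.9 reads per kb, against 74.0 in DM-only regions before scaling. The density bins thus partly set the direction, and no conclusion is drawn from the 23.3 points. The 43.4 points, from regions with a peak in both, show a difference between classes at matched reads. Called width was not matched, and weaker enrichment could change it as well. Bins rich in promoters also carry most weight, and the lowest bins showed no excess at promoters (0% against 1.26%, and 5.13% against 5.26%). The 43.4 points therefore do not decide for or against weaker enrichment. Signal did go with direction among regions with a peak in both. Above the upper quartile of the signal, 97.0% of promoters and 47.2% of other regions were lower. Below the lower quartile, 19.03% of promoters and 8.25% of other regions were lower. Among regions called in 1 library, the lowest of 20 bins of reads per called base was 100% lower in both classes. The highest bin was 48.1% lower at promoters and 2.57% elsewhere. The lowest bin lay at 61.6 reads per kb outside promoters, where the scaled DM-only regions hardly reach. These shares of regions called in 1 library therefore do not show whether signal went with direction. Weaker enrichment, peak calling and the diabetic group stay open, as 1 library per group confounds them.

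Listed regions of X were mostly called lower in DM, most of them from a peak in 1 library. The shares were 90.8% of 273 promoters, 63.7% of 226 introns and 85.3% of 313 distal intergenic regions, against 68.6%, 31.4% and 43.2% on the autosomes. Per called base, however, the 162 X regions with a peak in both had a median log2 ratio of 0.12 (0.54 on the autosomes), and the lower ones -0.0014. With classes weighted as on the autosomes, 76.6% of X regions were lower, against at most 52.1% on any of the 19 autosomes, which argues against the mix of classes. X lay 37.1 percentage points above the autosomal line of the share lower on genes per Mb, against a largest autosomal residual of 9.40, which argues against gene density. Embryos of a different sex in the 2 libraries could give such a shift, but of 5 sex-linked genes 0 had a listed region, which excludes nothing, and the 2 listed regions of Y, with control-only peaks of 63 and 72 reads, lie in Erdr1, a gene of the segment that X and Y share, so this cannot be told apart from the group. Neither the comparison by class nor that by gene density was matched on signal, so a different signal strength on X stays untested. Copy number of X in the 2 libraries was not tested, narrower called peaks stay open, and no part of the pattern can be called biological here.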
